A study of Macaca mulatta with 12 samples.

How the data were processed

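RNA from the ileum of 8 rhesus macaques was measured on 12 one-colour Affymetrix rhesus arrays. Per the labels, 4 animals carried simian immunodeficiency virus (SIV), given intravenously as SIVmac251, and were operated on 10 weeks after infection, and 4 were uninfected. At surgery, closed-off segments of ileum (ligated loops) received either Lactobacillus plantarum (LP) or the bacterial growth medium MRS as the control. The 3 groups of 4 arrays were LP loops of SIV+ animals (animals 1, 2, 6 and 7), MRS loops of the same SIV+ animals, and MRS loops of SIV− animals (animals 3, 4, 5 and 8). LP loops of SIV− animals were not analysed here.

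Per the labels' protocols, total RNA was isolated with a column kit and biotin-labelled cRNA was made from 6 µg of RNA. The deposited values are array intensities on a linear scale, 1 whole number per probe set and array, in a single table for all arrays. The software, background correction, summary of probes and normalization between arrays used by the authors are not given in the sources used here. The table held 52766 probe sets with intensities from 3 to 27224 and array medians from 26 to 30. Array medians differed by 0.131 on the log2 scale. Intensities carry no count of molecules, so precision is limited by the number of arrays.

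Values were taken as log2(intensity + 16), so that changes of dim genes are understated, and were quantile normalized between arrays because the array medians differed by more than 0.1. Of the probe sets, 24956 had 1 gene symbol in the platform annotation, 361 had several and 27449 were not listed in it and are unnamed here. Entrez identifiers of 24616 annotated probe sets matched the T2T-MMU8v2.0 gene table, which changed 0 symbols. Each of 14132 named genes was represented by its probe set with the highest mean over the 12 arrays. Genes in the lowest 25% of mean values were left out (floor 5.37 on the log2 scale, an intensity of 25.4), which left 10599 genes, of which 5542 had more than 1 probe set.

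Gene tests used limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided, Benjamini-Hochberg adjustment, threshold 0.05). The LP and MRS loops of SIV+ animals were compared with the animal as a block, because the labels give both arrays of a pair the same animal. SIV+ and SIV− animals were compared without a block, on 8 arrays each time. Deviations from the group means correlated, across genes, within every labelled pair, at 0.293 (animal 1), 0.263 (animal 2), 0.566 (animal 6) and 0.549 (animal 7). The array labelled LP 2 correlated more with MRS 1 (0.651), and LP 1 more with MRS 2 (0.451). Of 36 gene lists (17 pathways and 19 cell types) fixed beforehand, the 30 with at least 5 tested members were tested with limma's camera at an inter-gene correlation of 0.01. The same lists were tested with a correlation estimated per list, with fry, and with an exact two-sided permutation test of list means per array. That exact permutation test cannot go below p = 0.125 with 4 pairs or 0.0286 with 4 arrays against 4.

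The genes named in each comparison followed a fixed rule. Of genes past the threshold, up to 8 per direction with the largest fold change and a direction shared by all pairs, or with groups that did not overlap, were taken, filled up to 5 with the smallest unadjusted p where fewer than 5 passed. Up to 3 members with the smallest p of each list past the threshold were added, and in every comparison a fixed set of genes that included PPARA, CPT1A, PDK4, IL1B, CD4 and CD8A. Loci without a gene name were skipped.

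The correlation between the LP effect and the SIV effect used the MRS arrays of SIV+ animals in both effects, with opposite sign. It was set beside 100 simulations of unchanged groups with independent arrays and 100 that kept a correlation of 0.423 between arrays of 1 animal. It was also set beside effects taken from separate pairs of SIV+ animals, which share no array, and beside 100 random groupings of the 12 arrays. Counts of opposite signs were set beside 100 simulations with independent arrays and 100 random groupings of their own, added after the result was seen. Other splits of the arrays were refitted for each comparison. The grouping, the tests, the gene lists, the rule for named genes and most alternatives were chosen before the data were examined. These alternatives were no normalization or median centring, no filter or a filter on the dimmer 50%, the mean of a gene's probe sets, pseudocounts of 1 and 64, each animal left out, all 12 arrays with the animal as a random block, array weights, a trended robust variance prior and no block.

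A check of array identity was added after the data were examined. Probe sets were selected, without use of any label, whose 12 values fell into 2 levels at least 1.5 apart on the log2 scale, with at least 2 arrays on each side. The arrays were then compared by the levels they shared. Alternatives that leave out the arrays in doubt, and the permutation test of list means, were also added after the data were examined.

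The scripts were tested on simulated data over 10599 genes. For the LP comparison, 80% of genes changed by 1 on the log2 scale and 99% of those changed by 2 were recovered, with 9 false calls. For the SIV comparison the shares were 74% and 95%, with 5 false calls. For LP loops against uninfected animals they were 73% and 95%, with 6 false calls. The planted list was found each time, with 0 other lists. Simulated genes were independent, so this says nothing about false list calls among genes that vary together. The selection of 2-level probe sets found 199 of 200 planted ones, with 0 false. The count of opposite signs gave 99.6% for a planted SIV effect that LP arrays lacked and 56.0% for one that they kept. Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 were used for the remaining steps.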

Results

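Gene expression was measured in the ileum of SIV+ and SIV− rhesus macaques whose ligated ileal loops had received either L. plantarum (LP) or the medium MRS. Each of 3 groups held 4 arrays, as labelled: LP loops of SIV+ animals, MRS loops of SIV+ animals and MRS loops of SIV− animals. Array intensities were similar in range, with medians between 26 and 30. The design asks how SIV infection alters the ileum, how the infected ileum differs after LP, and how far the LP loop still differs from the uninfected ileum. Levels are given on the log2(intensity + 16) scale after quantile normalization.

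Probe sets that fell into 2 separate levels did not follow all of the animal labels. Of 52766 probe sets, 14 split the 12 arrays into 2 levels, among them probe sets of UGT2B33 and UGT3A1 (UDP-glycosyltransferases), CBLN4 and ROCK2, which were named after their values were seen. The arrays labelled as pairs of animals 6 and 7 differed at 0 of these 14. Those labelled as animal 1 differed at 3 and those labelled as animal 2 at 5. The array labelled LP 1 matched the array labelled SIV− 5 at all 14, MRS 1 matched LP 2 at all 14, and MRS 2 differed from SIV− 4 at 1. The last match did not hold at 9 further probe sets, where these arrays differed at 5, and SIV− 3 and SIV− 8, labelled as different animals, differed at only 2 of the 14. For example, the probe set MmuMitochon.10.1.S1_s_at read 7691 in LP 2, 48 in MRS 2 and 35 in SIV− 4. Across all 66 pairs of arrays the median was 5 differences, and 60 pairs differed at 3 or more. The 14 probe sets are not 14 separate markers. The 3 that set SIV− 3 and SIV− 8 apart all read CBLN4. Another 2 set MRS 2 and SIV− 4 apart, where MmuMitochon.10.1.S1_s_at was low too. The counts therefore overstate the number of independent differences and matches. The arrays were analysed as labelled, and counts without the arrays in question stand beside each comparison.

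**Figure D1:**
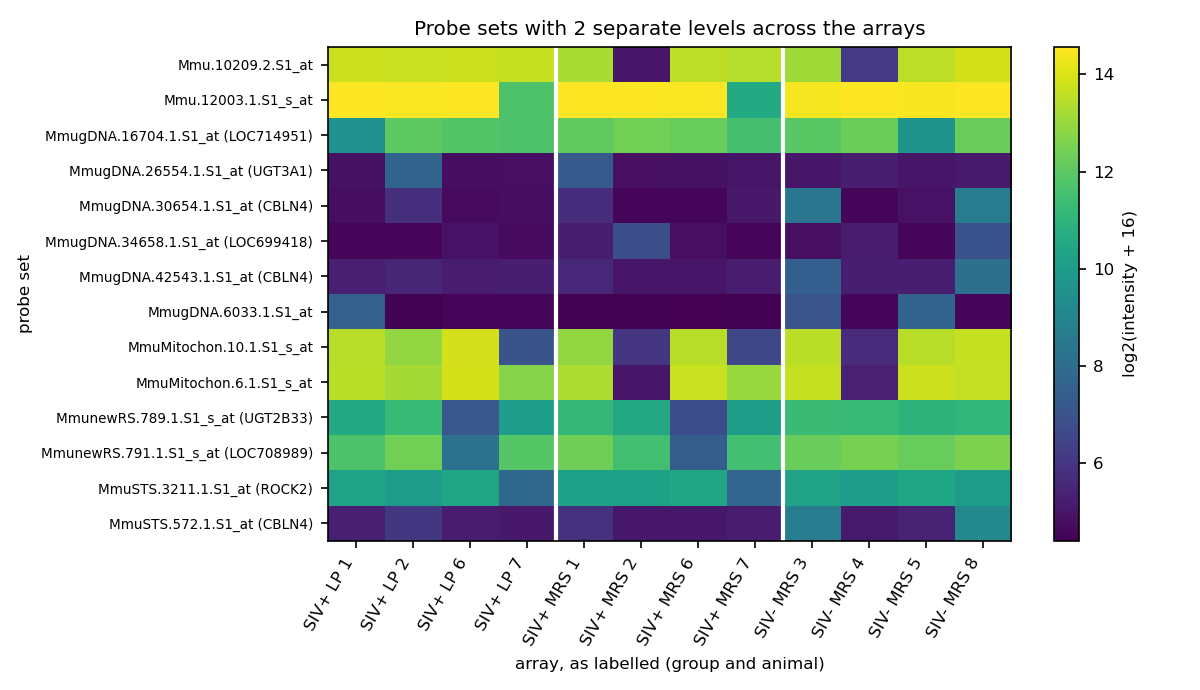
Values of the 14 probe sets that fell into 2 levels (rows, with the listed gene in brackets) in the 12 arrays (columns, named by labelled group and animal), as log2(intensity + 16) in colour. The labelled pairs of animals 6 and 7 share every level, while LP 1 and MRS 1 differ at 3 probe sets and LP 2 and MRS 2 at 5.

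In MRS loops, interferon-stimulated genes stood higher in SIV+ than in SIV− animals. IFI27 was 6.74-fold higher (10.22 ± 0.76 against 7.47 ± 0.63, SD, n = 4 each) and IFI44 7.42-fold higher (8.87 ± 1.02 against 5.98 ± 0.46), and BST2, which tethers budding virions to the cell surface, was 2.07-fold higher. Single genes of mucosal defence were also higher, namely LCN2 (a siderophore-binding antibacterial protein) 7.01-fold, the Paneth cell defensin DEFA6 9.95-fold and PIGR (which carries IgA across the epithelium) 2.14-fold. JCHAIN, the joining chain of polymeric antibodies, was 6.11-fold higher and CD8A 1.88-fold higher. The DEFA6 difference (11.40 ± 2.16 against 8.09 ± 0.37) was 5.24-fold without SIV+ animal 2 and 16.7-fold without SIV+ animal 7, that of LCN2 was 11.4-fold without SIV+ animal 1, and that of JCHAIN 9.20-fold without SIV− animal 5. Each of these 8 genes was higher in all 4 SIV+ arrays than in every SIV− array, yet with limma 0 of 10599 genes passed the adjusted threshold and their adjusted p lay between 0.334 and 0.467.

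The gene lists fixed beforehand gave 14 calls between SIV+ and SIV− animals, 11 higher and 3 lower. Of 28 interferon-stimulated genes tested, 25 were higher (median log2 fold change 1.03, camera adjusted p = 6.27e-15), and 15 passed when adjusted over the list alone. The list mean was 8.86 ± 0.53 in SIV+ and 7.79 ± 0.10 in SIV− animals (SD, n = 4 each). With an estimated correlation its adjusted p = 0.348. Adjustment of members over the list alone, here and below, does not allow for the number of lists tested. The interferon gamma and antigen presentation list had 16 of 18 members higher, with IDO1, the tryptophan-degrading enzyme, 3.16-fold, UBD 4.45-fold and the immunoproteasome subunit PSMB8 1.54-fold higher, and 3 passed when adjusted over the list alone (camera adjusted p = 1.07e-05). The antimicrobial and Paneth cell list had 14 of 17 higher, and 5 passed when adjusted over the list alone (camera adjusted p = 2.46e-05). For both lists the adjusted p = 0.348 with an estimated correlation. The median of the antimicrobial and Paneth cell list, 0.69, was 0.39 without SIV+ animal 2 and 1.13 without SIV+ animal 6, and UBD was 2.93-fold higher without SIV− animal 4.

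Lists of cytotoxic, plasma and macrophage cells, matrix, cell cycle and endothelium were also higher in SIV+ animals, while those of fibroblasts (median 0.27, adjusted p = 0.0602), smooth muscle (0.06, 0.658), B cells and germinal centres (0.19, 0.397), stem and crypt cells (0.11, 0.314) and goblet cells (0.26, 0.372) were not called. Cytotoxic T and NK cell genes had 12 of 14 members higher, with CD8B at 1.65-fold and NKG7 at 1.47-fold, and 3 passed when adjusted over the list alone (camera adjusted p = 3.46e-05, and 0.348 as the adjusted p with an estimated correlation). Plasma cell genes had 5 of 6 higher, with MZB1 at 1.74-fold and TNFRSF17 at 6.14 against a SIV− mean of 5.18, below the floor of 5.37 used for dim genes, and 3 passed when adjusted over the list alone (0.00235, and 0.348 with an estimated correlation, both adjusted p). Monocyte and macrophage genes had 9 of 12 higher, among them the complement genes C1QA at 2.22-fold and C1QB at 2.16-fold and the receptor CSF1R at 1.89-fold (adjusted p = 0.00169, and 0.394 with an estimated correlation). The NF-kB and IL-1 list had 14 of 24 higher, with CCL3 at 1.74-fold, NLRP3 at 1.53-fold and TLR2 at 1.35-fold (adjusted p = 0.00318, and 0.348 with an estimated correlation). Collagen and extracellular matrix genes had 19 of 21 higher, with COL1A2 at 2.07-fold, LOX (which crosslinks collagen) at 1.56-fold and COL6A3 at 1.62-fold, and 2 passed when adjusted over the list alone (adjusted p = 2.17e-06, and 0.348 with an estimated correlation). All 17 cell cycle genes were higher, with MCM2 at 1.82-fold, MCM3 at 1.68-fold and CCNE2 at 5.96 against a SIV− mean of 5.35, also below that floor (adjusted p = 3.04e-07, and 0.373 with an estimated correlation). Endothelial genes had 7 of 9 higher, with EMCN at 1.43-fold, PECAM1 at 1.39-fold and LYVE1, a marker of lymphatic endothelium, at 2.00-fold (adjusted p = 0.00536, and 0.368 with an estimated correlation). The unfolded protein and heat shock list had 16 of 18 higher, with HSPH1 at 1.67-fold, PDIA4 at 1.40-fold and PDIA6 at 1.55-fold, and 3 passed when adjusted over the list alone (adjusted p = 3.17e-04, and 0.348 with an estimated correlation). When adjusted over the list alone, 0 members passed in the macrophage, NF-kB, cell cycle and endothelial lists. All these calls held without any single animal, but their size rested in part on SIV− animal 8. Without it the median of the cell cycle list was 0.38 instead of 0.75 (MCM2 0.55 and MCM3 0.49), that of the endothelial list 0.23 instead of 0.48 (EMCN 0.33), that of the NF-kB list 0.15 instead of 0.41 and that of the collagen list 0.36 instead of 0.61, and C1QA was at 0.75 instead of 1.15. The macrophage median was 0.46 instead of 0.80 without SIV+ animal 2 (CSF1R 0.61 instead of 0.92), and the cytotoxic median, 0.44, was 0.27 without SIV+ animal 7 and 0.28 without SIV− animal 4.

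Of the lists, those of nutrient transport, enterocyte and junction genes were called as lower in SIV+ animals, with adjusted p from 0.368 to 0.443 with an estimated correlation. Nutrient transport and digestion genes had 19 of 21 members lower (median log2 fold change −0.38), with the peptide transporter SLC15A1 at −0.41, the fructose transporter SLC2A5 at −0.40 and CUBN, the receptor for vitamin B12 bound to intrinsic factor, at −0.82 (camera adjusted p = 8.93e-05, and 0.368 with an estimated correlation). All 14 enterocyte genes were lower, with the glucose transporter SLC5A1 at −0.50, APOA4 at −1.05 and FABP2 at −0.76 (adjusted p = 0.0118, and 0.443 with an estimated correlation). Tight and adherens junction genes had 17 of 22 lower, with CLDN23 at −0.33, F11R at −0.28 and JUP at −0.68 (adjusted p = 0.0463, and 0.368 with an estimated correlation). In these 3 lists 0 members passed when adjusted over the list alone. Without SIV+ animal 6 the nutrient median was −0.22, the enterocyte median −0.095 instead of −0.15 and APOA4 at −0.53, while without SIV+ animal 1 FABP2 was at −1.16. The enterocyte call was lost without SIV+ animal 6 (adjusted p = 0.135), and the call on tight and adherens junctions without SIV+ animal 1 (0.0538), 2 (0.0570) or 6 (0.123) or SIV− animal 5 (0.128). With array weights both calls were lost (0.0538 each), and that on tight and adherens junctions also with no filter (0.0713), with the dimmer 50% of genes left out (0.0512) and with the animal as a random block (0.0525). Where the junction call was lost, the median lay between −0.21 and −0.11 (main −0.15), and with array weights the enterocyte median was −0.13.

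Outside the lists, the genes with the smallest p that were higher in SIV+ animals included RPL24 (6.31-fold) and the complement protease gene C1S (3.35-fold). Those lower were SH3D21 (log2 fold change −0.87), LRRC75B (−0.68), PLEKHG6 (−0.53), the matrix gene MATN2 (−1.41) and RAB6B (−0.61). RPL24, a ribosomal protein gene, was read by 1 probe set, and further probe sets of C1QA, LOX, SLC2A5 and IL1B differed in direction from the one used. RPL24 read 9.14 in LP 1, labelled SIV+, within the SIV− range (9.10 to 10.41). It was close in arrays that matched at 2-level probe sets: LP 1 and SIV− 5 (9.37), and MRS 1 (11.64) and LP 2 (11.35). Infection and differences between animals were not told apart for it. PPARA (0.07, SE 0.16), its target CPT1A (−0.18, SE 0.15), PDK4 (0.07, SE 0.55), IL1B (0.94, SE 0.47, and 0.60 without SIV+ animal 1) and CD4 (0.08, SE 0.12) did not pass, and the list of PPAR alpha targets and fatty acid oxidation was not called (median −0.16, adjusted p = 0.119). The directions of PPARA, PDK4, IL1B and CD4 turned under at least 1 other setting.

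With limma, 969 genes had an unadjusted p under 0.05, 538 higher and 431 lower, and the lowest adjusted p was 0.334. The groups did not overlap for 514 genes, or 4.85%, where chance gives 2.86% on average. As genes vary together, a share above that average can arise by chance. Without the SIV+ array of animal 1, 11 genes passed, all of them higher and including RPL24, IFI27, C1S, IFI44 and LCN2, without SIV− animal 3 there were 2, and without SIV+ animal 2 there were 0, with 641 at an unadjusted p under 0.05. Without the MRS arrays of animals 2, 4 and 5, 0 genes and 16 lists passed, while the call on tight and adherens junctions was lost (adjusted p = 0.154) with a median of −0.17 (main −0.15).

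**Figure D2:**
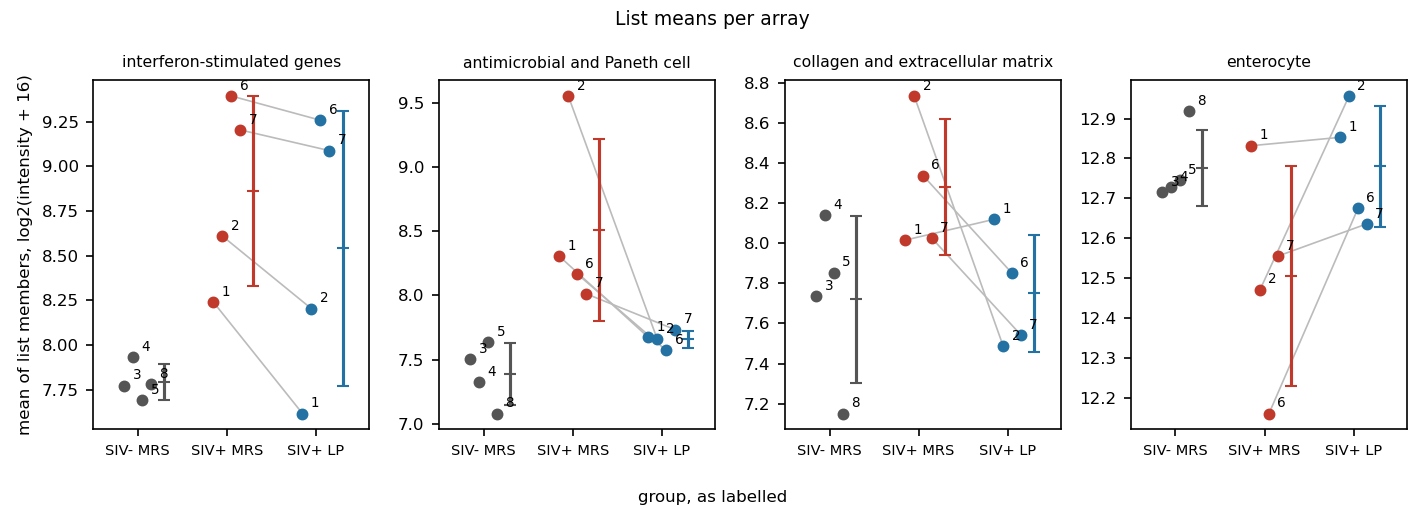
Mean of the tested members of 4 gene lists in each array (points, numbered by labelled animal), in log2(intensity + 16), for MRS loops of SIV− animals, MRS loops of SIV+ animals and LP loops of SIV+ animals; bars show the mean and SD of 4 arrays and grey lines join arrays labelled as the same animal. Interferon-stimulated genes average 7.79, 8.86 and 8.54 in these 3 groups, and the LP array of animal 1 lies at 7.62.

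In SIV+ animals, single genes of mucosal defence, matrix and goblet cells were lower in LP than in MRS loops, though none passed. LYZ (lysozyme) was 2.66-fold lower (8.04 ± 0.92 against 9.45 ± 1.13, SD, n = 4 each), DEFA6 9.55-fold lower (8.14 ± 0.52 against 11.40 ± 2.16) and the matrix proteoglycan genes LUM and DCN 2.30-fold and 1.84-fold lower. CLCA1 and TFF3, secreted by goblet cells, were 1.93-fold and 1.61-fold lower, and IFI27 was 2.67-fold lower. Among genes that were higher, the integrin subunit ITGB3 was 1.75-fold and the sodium-calcium exchanger SLC8A1 2.21-fold higher. DEFA6 was 4.31-fold lower without animal 2 and 17.9-fold lower without animal 7. Each of these 9 genes had the same direction in all 4 labelled pairs, but with limma 0 of 10599 genes passed, and their adjusted p lay between 0.102 and 0.111.

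Of the 30 lists, 11 were called between LP and MRS loops, 9 lower and 2 higher, and each of the 11 had adjusted p = 0.684 with an estimated correlation. Cell cycle genes had 16 of 17 members lower (median log2 fold change −0.43, camera adjusted p = 2.63e-05), among them the cyclin genes CCNB1 (−0.56) and CCNE2 (−0.51) and the kinase gene CDK1 (−0.59), and 9 passed when adjusted over the list alone. Collagen and extracellular matrix genes had 19 of 21 lower (median −0.59, adjusted p = 2.99e-05), including COL6A3 (−0.58), and 7 passed as lower and 1 as higher when adjusted over the list alone. Fibroblast genes had 6 of 8 lower (median −0.52, adjusted p = 0.0376), including DPT (−0.88), and 4 passed when adjusted over the list alone. Goblet cell genes had 8 of 9 lower (median −0.62, adjusted p = 9.97e-04), including ZG16 (−0.62), and 6 passed as lower and 1 as higher when adjusted over the list alone. Monocyte and macrophage genes had 9 of 12 lower (median −0.79, adjusted p = 0.00239), including CD14 (−0.61), the lipopolysaccharide co-receptor, VSIG4 (−0.85) and MS4A7 (−1.31), and 8 passed when adjusted over the list alone. Antimicrobial and Paneth cell genes had 12 of 17 lower (median −0.57, adjusted p = 0.00347), including RNASE6 (−1.36), and 6 passed when adjusted over the list alone. Without animal 2 the collagen median was −0.29 and the macrophage median −0.44 (MS4A7 −0.77 and VSIG4 −0.52), and without animal 7 the antimicrobial and Paneth cell median was −0.86. Smooth muscle genes had 9 of 10 lower (median −0.60, adjusted p = 0.0548), but the median was −0.03 without animal 7 (adjusted p = 0.696). Endothelial genes had 6 of 9 lower (median −0.15, adjusted p = 0.416), and neither list was called. Counts adjusted over the list alone do not set called lists apart, as 25.8% of all genes had an unadjusted p under 0.05 (limma). Lists that were not called had such members too: 4 lower for NF-kB and IL-1, 2 lower for plasma cells, and 2 lower and 1 higher for the tricarboxylic acid cycle.

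Interferon-stimulated genes had 20 of 28 members lower in LP loops (median −0.27, camera adjusted p = 0.00347), including TRIM22 (−0.95) and IFIT1 (−0.99), and 8 passed as lower and 1 as higher when adjusted over the list alone. Their list mean was lower in all 4 labelled pairs, at 8.54 ± 0.77 in LP and 8.86 ± 0.53 in MRS loops (SD, n = 4 each). The array labelled LP 1 had the lowest mean of all 12 arrays, at 7.62, against 7.69 in the array labelled SIV− 5, which it matched at the 14 probe sets with 2 levels. Without animal 1 the median was −0.13 and the interferon call was lost (adjusted p = 0.0638), as it was with animals 6 and 7 only (median −0.047, 0.182) and without the arrays LP 1 and MRS 2 in an unpaired fit (−0.077, 0.552). Respiratory chain genes had 22 of 28 lower (median −0.15, adjusted p = 0.0130), including ATP5F1B (−0.39), TFAM (−0.55), the mitochondrial transcription factor, and UQCRC2 (−0.37). Unfolded protein and heat shock genes had 16 of 18 lower (median −0.11, adjusted p = 0.0461), including HSPA8 (−0.41), PDIA6 (−0.46) and HSPH1 (−0.65). Without animal 6 the respiratory chain median was −0.074, PDIA6 was at −0.27 and HSPH1 at −0.28, and the unfolded protein median was −0.24 without animal 1 and −0.058 without animal 2. With an estimated correlation the adjusted p of these 3 lists was 0.684.

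Nutrient transport and digestion genes had 19 of 21 members higher in LP loops (median 0.32, camera adjusted p = 0.00239), including SLC15A1 (0.49), the glucose transporter SLC2A2 (0.57) and SLC2A5 (0.28). Enterocyte genes had 13 of 14 higher (median 0.24, adjusted p = 0.0155), including FABP2 (0.66), VIL1 (0.30), the actin bundler of the brush border, and APOA4 (0.55). With an estimated correlation the adjusted p of both was 0.684. The nutrient median was 0.20 without animal 2 and 0.17 without animal 6, and the enterocyte median 0.13 and 0.16. Without animal 2 FABP2 and APOA4 were both at 0.36, and without animal 6 APOA4 was at 0.37 and VIL1 at 0.20. In these lists and in the respiratory chain and unfolded protein lists, 0 members passed when adjusted over the list alone. Calls were lost when single animals were left out: the enterocyte call without animal 2 (adjusted p = 0.0677) or 6 (0.0555), the fibroblast call without animal 2 (0.0659), the mitochondrial respiratory chain call without animal 1 (0.0638) or 6 (0.0813), and the call on the unfolded protein and heat shock response without animal 2 (0.204) or 6 (0.287). With no block, the goblet cell and interferon-stimulated genes calls were lost (0.234 and 0.0749). Their medians (−0.62 and −0.27) cannot change with the block in this balanced design. The fibroblast call was lost without normalization between arrays (median −0.58, 0.0822), with median centring (−0.62, 0.108) and with no filter (−0.11, 0.105). With all 12 arrays and the animal as a random block, the goblet cell (0.118) and fibroblast (0.0527) calls were lost, with medians that this fit cannot change either. The call on the unfolded protein and heat shock response was lost with array weights (0.0883) and with pseudocount 1 (0.0519).

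The other genes with the smallest p in LP loops were GSDMB (0.63), a pore-forming gasdermin, INF2 (0.58) and MRM1 (0.57) among those higher, and TMEM150C (−1.26), the mitotic checkpoint gene BUB3 (−1.07), FBLN1 (−0.78) and ITIH5 (−0.67) among those lower. GSDMB, BUB3 and ITIH5 were read by 1 probe set each, and further probe sets of MRM1, TRIM22, ATP5F1B, TFAM, HSPH1, SLC2A5, DCN, VIL1, MS4A7, CPT1A and IL1B differed in direction from the one used. PDK4, which restrains glucose oxidation, was at −0.89 (SE 0.21), IL1B at −0.75 (SE 0.24) and CD8A at −0.46 (SE 0.11), with lower values in all 4 pairs and adjusted p between 0.105 and 0.133 (limma). PPARA (0.01, SE 0.16), CPT1A (0.13, SE 0.16) and CD4 (−0.17, SE 0.13, near the floor for dim genes) did not pass, and the direction of PPARA, CPT1A and IL1B turned under another setting. The list of PPAR alpha targets and fatty acid oxidation was not called (median 0.10, adjusted p = 0.606).

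With limma, 2730 genes had an unadjusted p under 0.05 and the lowest adjusted p was 0.102, with 1809 genes under 0.15. The direction was shared by all 4 labelled pairs for 3887 genes, or 36.7%, where chance gives 12.5% on average. Genes vary together, so this gap is no measure of departure from chance. These 2730 were 1396 higher and 1334 lower, but the split depended on the scaling: it was 757 and 1876 without normalization and 496 and 2256 with median centring, which moved the median of all genes by −0.11, from 0.04 to −0.07. The 11 called lists kept their direction under both scalings. In a fit with no block 1579 genes had an unadjusted p under 0.05, without animal 6 there were 1636, and 0 passed in either. With the labelled animals 6 and 7 only, 478 genes (53 higher and 425 lower) and 13 lists passed, in a fit with 1 residual degree of freedom per gene. Without the arrays LP 1 and MRS 2, unpaired, 0 genes passed (831 at an unadjusted p under 0.05) and 9 lists, with the calls on goblet cell (adjusted p = 0.203), antimicrobial and Paneth cell (0.0713) and enterocyte genes (0.0713) also lost. The medians of these 3 lists were then −0.63 (main −0.62), −0.45 (−0.57) and 0.20 (0.24). This unpaired fit also gave up the pairing of animals 6 and 7. The fall from 2730 to 831 genes can therefore not be credited to the arrays left out alone.

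Between the LP loops of SIV+ animals and the MRS loops of SIV− animals, the interferon lists were called as higher in the LP loops, whose arrays were widely spread. The mean of the interferon-stimulated genes was 8.54 ± 0.77 in LP loops and 7.79 ± 0.10 in SIV− animals (SD, n = 4 each). It was higher in 3 of 4 LP arrays, while LP 1, at 7.62, lay below all 4 SIV− arrays, which also enter the SIV comparison. For the interferon gamma list LP 1 (9.29) lay within the SIV− range (9.26 to 9.48). Interferon-stimulated genes had 27 of 28 members higher (median log2 fold change 0.63, camera adjusted p = 5.01e-11, and 0.804 as adjusted p with an estimated correlation), with BST2 at 1.56-fold, EPSTI1 at 2.20-fold and OAS3 at 2.69-fold. The interferon gamma and antigen presentation list had 15 of 18 higher (median 0.39, adjusted p = 5.12e-04, and 0.804 with an estimated correlation), with GBP2 at 1.66-fold, UBD at 3.24-fold and TAPBP at 1.35-fold. Cytotoxic T and NK cell genes had 13 of 14 higher (0.0114 as adjusted p, and 0.804 with an estimated correlation), with CD8A and CD8B at 1.37-fold and 1.36-fold and the cytolytic gene GNLY at 1.62-fold. The interferon gamma median was 0.25 without SIV+ animal 6, where TAPBP was 1.22-fold higher, and UBD was 2.14-fold higher without SIV− animal 4. The cytotoxic median, 0.23, was 0.36 without SIV+ animal 1 and 0.11 without SIV− animal 4, where GNLY was at 0.46 instead of 0.70 and CD8B at 0.28 instead of 0.44. All 7 called lists had adjusted p = 0.804 with an estimated correlation, and 0 members of any passed when adjusted over the list alone.

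The other 4 called lists depended on single arrays, and their adjusted p too was 0.804 with an estimated correlation. Cell cycle genes had 16 of 17 higher (median 0.35, adjusted p = 0.0254, with MCM5 at 0.38, TOP2A at 0.60 and AURKB at 0.24), and the call was lost without SIV+ animal 1 (adjusted p = 0.0710) or 2 (0.143) or SIV− animal 4 (0.214), while the direction turned without SIV− animal 8 (0.889). Endothelial cell genes had 9 of 9 higher (adjusted p = 0.0484, with PECAM1 at 0.33, EMCN at 0.29 and CDH5 at 0.42), and lost the call without SIV+ animal 1 (0.111), 6 (0.158) or 7 (0.298) or SIV− animal 8 (0.668). Smooth muscle genes had 9 of 10 lower (median −0.50, adjusted p = 0.0318, with SYNM at −1.01, CALD1 at −0.47 and TPM2 at −0.65), and lost it without SIV+ animal 1 (0.0628), 2 (0.101) or 7 (0.879) or SIV− animal 4 (0.338). Mitochondrial respiratory chain genes had 21 of 28 lower (median −0.10, adjusted p = 0.0484, with UQCRC2 at −0.42, COX7A2 at −0.23 and ATP5MC1, which was higher, at 0.29), and lost it without SIV+ animal 1 (0.0710), 6 (0.495) or 7 (0.235) or SIV− animal 3 (0.777). Without SIV− animal 8 the endothelial median was 0.099 instead of 0.29 (CDH5 0.061), MCM5 was at 0.18 and TOP2A at 0.21, and without SIV+ animal 7 the smooth muscle median was −0.088 (SYNM −0.25, CALD1 −0.14 and TPM2 −0.18). Without SIV+ animal 6 the smooth muscle median was larger, at −0.83 (CALD1 −0.71 and TPM2 −1.01). The respiratory chain median was −0.021 without SIV+ animal 6 (COX7A2 −0.11), −0.063 without SIV+ animal 7 and −0.034 without SIV− animal 3. Without SIV− animal 4 the cell cycle median was 0.18 (AURKB 0.14) and the smooth muscle median −0.29. The cytotoxic T and NK cell call was lost without SIV+ animal 6 (0.0519) or SIV− animal 4 (0.214). With array weights the interferon gamma (0.111), cytotoxic (0.159), cell cycle (0.242), respiratory chain (0.211) and endothelial (0.793) calls were lost. With the mean of a gene's probe sets the cell cycle (0.0846), smooth muscle (0.0898), respiratory chain (0.217) and endothelial (0.0849) calls were lost, and with no filter the cell cycle (0.0520), smooth muscle (0.0787) and endothelial (0.0989) calls. With all 12 arrays and the animal as a random block the smooth muscle (0.0718), respiratory chain (0.0565) and endothelial (0.0565) calls were lost, with pseudocount 1 the respiratory chain and endothelial calls (0.0527 each), and with pseudocount 64 the endothelial call (0.0631).

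Single genes with the smallest p in this comparison were the mucin MUC1 (1.51-fold), NECTIN2 (1.30-fold), the necroptosis effector MLKL (1.74-fold), the fatty acid elongase ELOVL6 (1.44-fold) and ITGB3 (1.72-fold) among those higher in the LP loops. RAB5A (log2 fold change −0.77), the eosinophil-attracting chemokine CCL24 (−0.67), YWHAQ (−0.54), FLOT1 (−0.51) and TSNAX (−0.67) were lower. None of these 10 passed, with adjusted p = 0.996 for each (limma). Further probe sets of NECTIN2, RAB5A, ITGB3, CD8A, CD8B, CALD1, TPM2, PECAM1 and EMCN differed in direction from the one used. PPARA (0.08), CPT1A (−0.05), PDK4 (−0.83, and −0.49 without SIV+ animal 1 or 6 and −1.25 without SIV+ animal 7), IL1B (0.19) and CD4 (−0.08, near the floor for dim genes) did not pass either, and the directions of PPARA, CPT1A, IL1B, CD4 and TPM2 turned under another setting. With limma 0 genes passed and 317 had an unadjusted p under 0.05, 190 higher and 127 lower. That split was 74 higher and 173 lower with median centring and 110 and 142 without normalization, and the count was 180 without SIV+ animal 6. Groups did not overlap for 230 genes, or 2.17%, where chance gives 2.86% on average. Called lists numbered 3 without SIV+ animal 1 and 4 without SIV− animal 4. Without the LP array of animal 1 and the MRS arrays of animals 4 and 5, 0 genes and 10 lists passed, while the smooth muscle call was lost (median −0.39, adjusted p = 0.215).

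Across 10599 genes, the LP effect in SIV+ animals ran opposite to the SIV effect in MRS loops (Pearson r = −0.764 across genes, which are not independent replicates). The same MRS arrays enter both effects with opposite sign, and simulated unchanged groups with independent arrays gave a mean r of −0.506 (from −0.582 to −0.450). Simulations that kept the correlation between arrays of 1 animal gave −0.377 (from −0.428 to −0.339). The covariance was −0.0740 against −0.0267 in the simulations with independent arrays, a difference of −0.0473. With each effect taken from a separate pair of SIV+ animals, so that no array was shared, the median r over the 6 such splits was −0.499 (from −0.556 to −0.469), against simulated values from −0.0886 to 0.0382. Of the 969 genes at an unadjusted p under 0.05 in the SIV comparison, 944 (97.4%) had the opposite sign in the LP comparison, against a mean of 87.4% in simulated unchanged groups that shared arrays in the same way (highest 91.7%), and 23 of 101 groupings of the arrays (the labelled one and 100 random ones) were as high. Genes higher with SIV and lower with LP numbered 326, where independent lists give 67.7 and the simulations 52.2 (highest 70), and 6 of these 101 groupings gave as many. Those lower with SIV and higher with LP numbered 217, where independent lists give 56.8 and the simulations 52.1 (highest 68), and 5 of the 101 gave as many. The simulations had fewer genes at an unadjusted p under 0.05 in the SIV comparison (mean 539, against 969). Their counts of shared genes are therefore lower for that reason too, and the gap to 326 and 217 is no measure of reversal. Simulated genes were independent, which makes their range too narrow. Of the 30 list medians 27 had opposite signs, against 18.9 on average in the simulations (highest 25), and 3 of the 101 gave as many. These simulations and groupings were added after the result was seen. Signs were also opposite for all 8 lists called in both comparisons, which were interferon-stimulated, cell cycle, collagen and matrix, antimicrobial and Paneth cell, monocyte and macrophage, unfolded protein, nutrient transport and enterocyte genes. Opposite signs of such lists are expected from the shared arrays: in the random groupings 328 of 358 lists called in both were opposite, and 10 of the 101 groupings gave at least 8. Some lists also share members, so they do not count as separate evidence. SLC5A1 and APOA4 are in the nutrient transport and enterocyte lists, and LUM and DCN in the collagen and fibroblast lists. Without the arrays LP 1, MRS 2, MRS 4 and MRS 5 the correlation was −0.668, where simulated unchanged groups with independent arrays gave a mean of −0.452 (from −0.559 to −0.400), as MRS arrays were still shared.

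**Figure D3:**
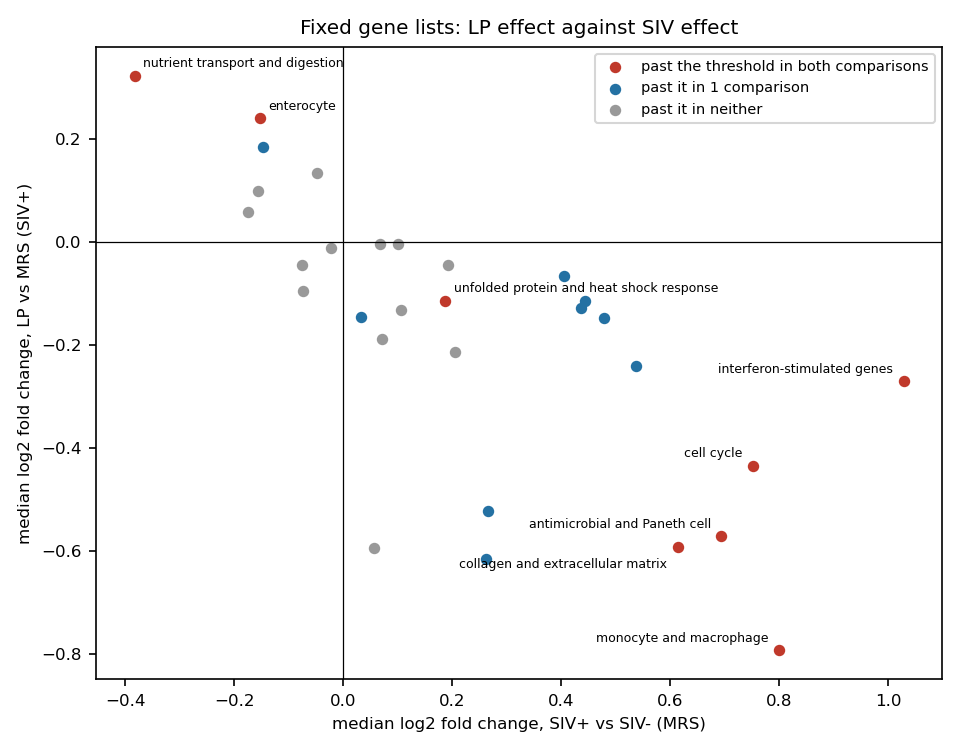
Median log2 fold change of each of the 30 tested gene lists between SIV+ and SIV− MRS loops (x axis) and between LP and MRS loops of SIV+ animals (y axis), coloured by whether the list passed the camera threshold; both axes use the MRS arrays of SIV+ animals. All 8 lists past the threshold in both comparisons, named in the plot, lie in the upper left or lower right quadrant.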

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

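The check of each group for an array standing apart was fixed before the data were examined. In a group of 4 arrays, an array was noted when its gap to the nearest other array as a share of the group's range exceeded Dixon's critical value at the 95% level. This gave 23 notes over 411 groups of 4 arrays (5.6%), where chance gives about 1 in 20. They concerned 5 lists and 18 genes, and 9 of the 23 lay in the array SIV− MRS 8, 4 in SIV+ MRS 2 and 3 each in SIV+ MRS 1 and LP 6. No explanation was tested for them.

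In SIV− MRS 8, endothelial genes averaged 6.30 where the nearest other array of the group had 6.95, and enterocyte genes averaged 12.92 against 12.74. In the same array CD14 read 5.93 (nearest 6.98), C1QA 6.76 (8.30), CDH5 5.73 (7.08), PIGR 6.62 (7.23), HSPH1 7.81 (8.23), TSNAX 7.14 (7.31) and CUBN 8.42 (8.05). In SIV+ MRS 2, RNASE6 read 9.59 (nearest 7.92), TNFRSF17 6.99 (5.95), CD4 5.82 (5.50) and RAB6B 6.56 (6.81).

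In SIV+ MRS 1, IFI27 read 9.10 (nearest 10.50) and OAS3 6.70 (7.90), both lower than in the other MRS loops of SIV+ animals, and tuft cell genes averaged 6.51 (6.34). In LP 6, SLC2A5 read 11.81 (nearest 11.36), COX7A2 8.85 (9.30) and TAPBP 11.76 (11.20). In LP 2 the PPAR alpha and fatty acid oxidation list averaged 9.76 (9.40), in LP 1 LRRC75B read 8.47 (8.10), in SIV− MRS 3 MATN2 read 8.97 (9.68), and in SIV− MRS 5 B cell and germinal centre genes averaged 7.53 (6.72).

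Outside the annotated genes, a probe set with no gene listed had an intensity of 16 in LP 7, where the SIV− arrays reached at most 7, and 5 of the 8 SIV+ arrays lay above that level. Of the 8 other probe sets of the same sequence entry, 3 had 0 SIV+ arrays above the highest SIV− array, 2 had 1, 2 had 2 and 1 had 3. Of that first probe set all intensities are below the floor of 25.4 used for genes.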

How the results depend on the processing

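The alternatives without the arrays in doubt (animals 6 and 7 only, and those without LP 1, MRS 2, MRS 4 or MRS 5) and the permutation test of list means were chosen after the data were seen. With limma, 0 genes passed between LP and MRS loops in all settings but one: 478 passed (53 higher, 425 lower) with animals 6 and 7 only, where 1 residual degree of freedom was left. Leaving out each animal gave 0 genes there, and 0 to 11 between SIV+ and SIV− animals (11 without SIV+ animal 1, 2 without SIV− animal 3). Between LP loops and uninfected animals 0 passed in all settings. At an unadjusted p under 0.05, the LP count of 2730 was 1765 with the dimmer 50% of genes left out, and the count of 317 against uninfected animals was 490 with no filter and 187 without LP 1, MRS 4 and MRS 5. The called lists numbered 0 in all 3 comparisons with an estimated correlation (lowest adjusted p 0.684, 0.348 and 0.804 for LP, SIV and LP against uninfected animals), with fry's directional test (0.317, 0.162 and 0.865) and with the exact permutation test (0.375, 0.122 and 1), against 11, 14 and 7 with camera. The permutation test cannot go below 0.125 with 4 pairs or 0.0286 with 4 arrays against 4, before adjustment. In the SIV comparison 7 lists, interferon-stimulated genes among them, were at that limit, which gave the adjusted 0.122. With so few arrays the absence of calls from this test is therefore no evidence against these lists. Fry's mixed test called 8, 6 and 0 lists. Leaving out each animal gave 9 to 14, 13 to 15 and 3 to 10 lists. LP lists against uninfected animals numbered 4 with no filter, 4 with the mean of probe sets, 4 with all 12 arrays and the animal as a random block, and 2 with array weights. Without the replicate block, the LP comparison gave 0 genes and 9 lists, losing the goblet cell and interferon-stimulated calls. The value of r (−0.764) is built from group means, so the block cannot change it. Leaving out each animal moved r between −0.827 and −0.608 (−0.608 without SIV+ animal 2 and −0.619 without SIV− animal 8). Of the called lists, 154, 240 and 89 results kept direction and call over the settings that use camera with its fixed correlation, 22, 11 and 36 lost the call, and 0, 0 and 1 turned. Of the named genes, 747, 1001 and 670 results stayed on their side, 17, 5 and 0 came to pass, and 9, 8 and 9 turned. Between LP and MRS loops, PPARA turned to −0.11 without normalization, −0.15 with median centring and −0.034 with array weights, and lay between −0.11 and 0.19 when each animal was left out (below 0 without animal 2 or 6). IL1B turned to 0.089 with pseudocount 1. CPT1A turned to −0.17 with animals 6 and 7 only and −0.012 without LP 1 and MRS 2, and lay between −0.059 (without animal 2) and 0.27. Between SIV+ and SIV− animals, IL1B turned to −0.011 with pseudocount 1. Without the MRS arrays of animals 2, 4 and 5, PPARA turned to −0.023 and PDK4 to −0.57. When each animal was left out, PPARA lay between −0.086 (without SIV+ animal 1) and 0.16, PDK4 between −0.27 (without SIV+ animal 7) and 0.58, and CD4 between −0.00072 (without SIV+ animal 2) and 0.14. Against uninfected animals, PPARA turned to −0.016 with median centring, TPM2 to 0.098 with the mean of probe sets and CPT1A to 0.15 with array weights. When each animal was left out, PPARA lay between −0.047 and 0.17, CPT1A between −0.21 and 0.19, IL1B between −0.18 and 0.47, CD4 between −0.16 and 0.010, and the cell cycle list between −0.0027 (without SIV− animal 8) and 0.57. The cause was not tested. The median, mean and test of a list differed in sign for 0 called lists. Values near background are compressed by the pseudocount of 16, which limits what dim genes can show.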

Other observations

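The tests of the array labels, of the covariance without 4 arrays, of cell composition and of normalization were chosen after the result was seen, while the splits with no shared array and the other splits of the arrays were fixed before.

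Enteroendocrine and mast cell genes, whose lists had under 5 tested members and were not tested as lists, went both ways in LP against MRS loops of SIV+ animals. CHGB, a secretory granule protein gene, was at −1.31 (SE 0.18) on the log2 scale, GCG, which encodes proglucagon, at −1.80 (SE 0.45) and SCG2 at −0.92 (SE 0.23), while PYY was at 0.06 (SE 0.13). The mast cell protease gene CPA3 was at −1.19 (SE 0.25) and KIT at −0.47 (SE 0.13), while GATA2 was at 0.20 (SE 0.13). None passed over all genes (limma adjusted p between 0.102 and 0.117 for the 5 lower genes). Between SIV+ and SIV− animals CPA3 was at 1.42 (SE 0.48), GCG at 1.55 (SE 0.75) and KIT at 0.03 (SE 0.27), with adjusted p of 0.479, 0.557 and 0.969 (limma).

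Neutrophil genes were at −0.70 (MMP9, SE 0.30), −0.54 (S100A8, SE 0.25), −0.57 (S100A9, SE 0.32) and −0.17 (CSF3R, SE 0.12) in LP loops, with adjusted p between 0.198 and 0.378 (limma). Among erythroid genes, HBA read 10.37 in SIV+ MRS 2 and 6.10 to 7.97 in every other array. HBB read 6.69 there and at most 5.81 elsewhere, while ALAS2 (6.17) lay within the range of the other arrays (6.12 to 6.48). Whether that sample held more blood was not tested. T cell genes went both ways, with CD5 at 0.20 (SE 0.17), CD6 at 0.25 (SE 0.14), ICOS at −0.21 (SE 0.11) and TRAT1 at −0.40 (SE 0.22). CCR6 (0.00050, SE 0.12) and CD40LG (0.11, SE 0.13) did not pass either. ICOS (5.21 to 5.98 over the arrays) and CD40LG (5.29 to 6.06) read near the floor of 5.37, where changes are compressed.

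The arrays labelled as animals 1 and 2 differed within the pair at probe sets with 2 separate levels. A failed MRS 2 array would leave pair 1 without differences, and it differed at 3 of 14, so that it would not account for both pairs. MRS 2 did stand apart alone at 18 further probe sets, against 0 to 2 for every other array. A problem of that array was therefore not excluded at those probe sets. An effect of L. plantarum would also part pairs 6 and 7, which differed at 0. At 9 further probe sets with smaller gaps, some of them part of an earlier look, pairs 1 and 2 differed 11 times in total (7 and 4), against 6 for the 3 pairs of arrays that had matched. There LP 1 and SIV− 5 differed at 0 and MRS 1 and LP 2 at 1, but MRS 2 and SIV− 4 at 5, so that the last match did not hold. A mislabelled sample among these arrays is a candidate explanation that these tests leave standing. A difference between loops of 1 animal would part a labelled pair, but would not make its arrays match those of another animal. LP 1 and SIV− 5 differed at 0 of 14 and 0 of 9, and MRS 1 and LP 2 at 0 of 14 and 1 of 9. These values argue against such a difference for LP 1, MRS 1 and LP 2. For MRS 2, whose match did not hold, some probe sets named MmuMitochon bear on it. They read 34, 139, 16 and 48 in MRS 2, 105, 716, 24 and 35 in SIV− 4, and 6932, 11203, 9441 and 7691 in LP 2. The others named so read 3944 and 32 in MRS 2, against 6576 and 57 in LP 2. A fault of MRS 2 or a loop difference would not make SIV− 4 low too. The low values argue against both causes, for those probe sets only. For LP 1 and SIV− 5, the means of the interferon-stimulated genes were 7.62 and 7.69. The other SIV− arrays lay between 7.77 and 7.93, and every other SIV+ array at 8.20 or higher. If both came from 1 animal, these values argue against a wrong label of SIV− 5 and put the SIV+ label of LP 1 in doubt. That rests on 1 list and on group levels taken from the labels. For MRS 1 and LP 2, which array would carry the wrong label stays open.

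The LP effect ran opposite to the SIV effect across genes. MRS arrays shared by both effects do not account for all of it, since the median r over 6 splits with no shared array was −0.499, below every simulated value (lowest −0.0886) and below the 100 random groupings (lowest −0.477). Over all arrays, r as low as −0.764 was reached in 7 of 101 groupings, the labelled one and 100 random ones (lowest other −0.847), so chance was not excluded for r itself. Without LP 1, MRS 2, MRS 4 and MRS 5 the covariance was −0.0718, below the simulated range (lowest −0.0504), but simulated genes were independent, which made that range too narrow, and 12 of these 101 groupings, a comparison added after the result was seen, were as low (lowest other −0.141). A mislabelled sample therefore stays open here, as does a shift of LP loops towards uninfected tissue, which may be followed up once the labels are settled.

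Collagen, fibroblast, macrophage and goblet lists were called as lower and nutrient transport and enterocyte lists as higher in LP loops, while each had adjusted p = 0.684 with an estimated correlation and the smooth muscle and endothelial lists were not called. A larger share of enterocytes that diluted all other cells alike would lower fibroblast and endothelial genes equally, but fibroblast minus endothelial averaged −0.3775 over the 4 pairs (SD 0.2165). Without normalization between arrays the medians stayed close to the main ones: −0.68 for collagen and extracellular matrix, −0.85 for monocyte and macrophage, −0.64 for goblet cell, 0.24 for enterocyte and 0.27 for nutrient transport genes. The 12 lists that passed without it included smooth muscle and junction genes, which did not pass in the main fit, but not fibroblast genes (median −0.58, adjusted p = 0.0822). A change in the make-up of particular cell types, a different depth of sampling and expression within cells may each contribute, and were not told apart by these tests.

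Other splits of the arrays were refitted for each comparison. As 0 genes passed in each comparison, every split gave as many (8 of 8, 35 of 35 and 35 of 35), and these counts say nothing about chance. For LP against MRS loops 4 of 8 splits gave as many lists as 11 (highest other 18) and 1 of 8 as many genes at an unadjusted p under 0.05 as 2730 (highest other 788), but 8 splits are too few for a share under 0.05. For SIV+ against SIV− animals 2 of 35 gave as many lists as 14 (highest other 17) and 4 of 35 as many such genes as 969 (highest other 2378), so chance was not excluded. For LP loops against uninfected animals 14 of 35 gave as many lists as 7 (highest other 14) and 23 of 35 as many such genes as 317 (highest other 3103), and chance was not excluded. The splits with the most genes, 158 for SIV and 793 for LP against uninfected animals (0 for LP against MRS), both set animals 1, 2, 3 and 5 against 4, 6, 7 and 8. The comparisons share the 4 SIV− arrays, and no cause of this was tested.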
